A study of Rattus norvegicus with 21 samples.

How the data were processed

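Gene expression was measured in rat liver before treatment (0 h) and at 6 times, from 3 to 72 h, after carbon tetrachloride, a solvent that hepatocytes convert to reactive radicals and that is used to produce acute hepatic failure. Per the labels, the animals were Sprague-Dawley rats, the tissue came from the middle of the right lobe, and biotin-labelled cRNA was made from total RNA and hybridised to Affymetrix whole-genome rat expression arrays. There were 21 arrays, 3 at each of 7 time points. The labels call the 3 arrays of a time point technical replicates, and the number of animals behind a time point is not given in the sources used here. All p-values below therefore cover only the spread between arrays of a time point. They do not cover the spread between rats, and time point and animal cannot be told apart. For arrays no read depth applies, and the number of arrays limits the precision.

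The deposited signals are intensity values on a linear scale, made by the authors with GCOS 2.0, per the submitters' processing notes. The trimmed mean of each array, with 2% removed at each end, lay between 500.2 and 500.3 in all 21 arrays, so the deposited signals share 1 scale. The same signals were found in a workbook and in the matrix of values, where they differed by at most 0.5. The authors also deposited 9 log2 ratios per time point, 1 for each pair of a treated and a 0 h array, in steps of 0.1, per the file headers and the values. The authors' linear ratio columns, named so per the file headers, hold the same comparisons as fold values. Both kinds of ratio were used here only to compare their sign and size with the fits made from the signals. The files hold no detection calls, so a gene's absence from the tissue cannot be judged from them. The part of the rule for named genes that asks for detected genes could therefore not be applied.

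The arrays hold 31099 probe sets, of which 57 are controls. Probe sets were named through the accession or symbol that the files give and a table of current rat RefSeq genes of the GRCr8 assembly. Of the probe sets, 19863 had 1 symbol, 23 had several and 11121 had none. For 35 more the accession and the symbol pointed to different genes, and these were left unnamed. The named probe sets stand for 13881 genes. Names came from the accession for 3041 probe sets, from a current symbol for 12346 and from a synonym for 2984, and the symbol in the files was kept for 1492. No coordinates are given, since the array's own design was used without a genome.

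Signals under 1 were set to 1 and log2 was taken, with no further normalization, because the arrays already shared their trimmed mean. Probe sets whose mean log2 signal over all arrays was above the 40th percentile were tested, which is a signal of 69.4. This left 18625 probe sets and 10405 genes. Where a gene had several probe sets, the one with the highest mean log2 signal stood for it. In 2675 genes with several tested probe sets, between 1 and 9 genes per time point had probe sets called in opposite directions, among them Atp5if1, Smpdl3b and Gldc.

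A linear model with 1 mean per time point was fitted to all 21 arrays with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, and tables were read with data.table (version 1.17.8). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all tested probe sets of the comparison, with a log2 fold change of at least 1 in size. Each time was compared with 0 h. The 24 h arrays were also compared with the 6 h arrays, and the 72 h arrays with the 24 h arrays. A moderated F-test covered the 6 comparisons with 0 h together. A further fit took 1 mean per time point as a single value and used pairs of adjacent times (3 and 6 h, 12 and 24 h, 48 and 72 h) as phases, with 3 residual degrees of freedom. The steps were tested on simulated data made from the real probe sets. In a simulated comparison of 24 h with 0 h over 18625 probe sets, 78%, 74%, 84% and 98% of the probe sets changed by a log2 fold change of 1.2, 1.5, 2 and 3 were recovered, with 1 false call. Only 50 probe sets were changed per size, and the noise was normal and independent between probe sets. Spread between rats and effects shared by an array were not simulated. These rates therefore need not hold for the real comparisons, where far more genes were called.

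The 26 gene lists were fixed before the data were examined, as were the tests, the thresholds, the rule for named genes and most alternatives. They cover cytochrome P450 and drug metabolism, bile acids, urea cycle and amino acid catabolism, fatty acid oxidation, cholesterol synthesis, gluconeogenesis and glycogen, targets of NRF2, endoplasmic reticulum stress, heat shock, immediate early genes, ribosome biogenesis, acute phase and secreted proteins, cytokines, proliferation, targets of p53, zones of the liver lobule and markers of other liver cells. They were tested with limma's camera at its preset correlation between genes of 0.01, 2-sided, on 1 probe set per gene, with Benjamini-Hochberg adjustment over 26 lists and 6 comparisons with 0 h. Some genes are in more than 1 list. Cyp7a1 is in the bile acid and pericentral lists, Sds and Otc in the urea cycle and periportal lists, and Atf3 in the stress response and immediate early lists. Calls of lists that share members are not independent. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Named genes were the 6 largest rises and the 6 largest falls among called genes at each time (leaving out symbols of uncharacterised loci), up to 4 called members of each list at the time of its largest median, and a panel of 17 genes at all times.

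The alternatives were quantile normalization, median centring, 32 added to each signal before log2, no filter or a filter at the 60th percentile, no intensity trend, no fold limit, the probe set with the largest variance, only the arrays of the 2 times compared, the signals of the workbook, the replicate number as a block and leaving out each array. Added after seeing the data were array weights, a filter at 1 or more time points, and scaling of each array to its 12 poly-A control probe sets (dap, thr, phe and lys), which stand for bacterial transcripts with poly-A tails that are usually added to the RNA before labelling. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.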

Results

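Rat liver was profiled before and at 6 times after carbon tetrachloride, with 3 arrays at each of 7 time points, to follow how the expressed genes change in acute hepatic failure. The arrays of a time point are technical replicates per the labels, so the tests below compare time points against the spread between arrays and not between rats. Across probe sets with a mean signal over 200, log2 signals of arrays of 1 time point correlated at r = 0.985 to 0.992. Dimmer probe sets, some of them tested, are not in these correlations. The exception was replicate 3 at 6 h, which reached 0.934 and 0.937 with its partners. On that array the 100 brightest probe sets held 31.9% of the summed signal, against 10.9% to 14.8% on the other 20 arrays. Its highest signal was 248092, against 36340 to 61174 elsewhere. The median SD of a probe set between the arrays of a time point was 0.305 (log2) at 6 h and 0.125 to 0.156 at the other times.

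**Figure D1:**
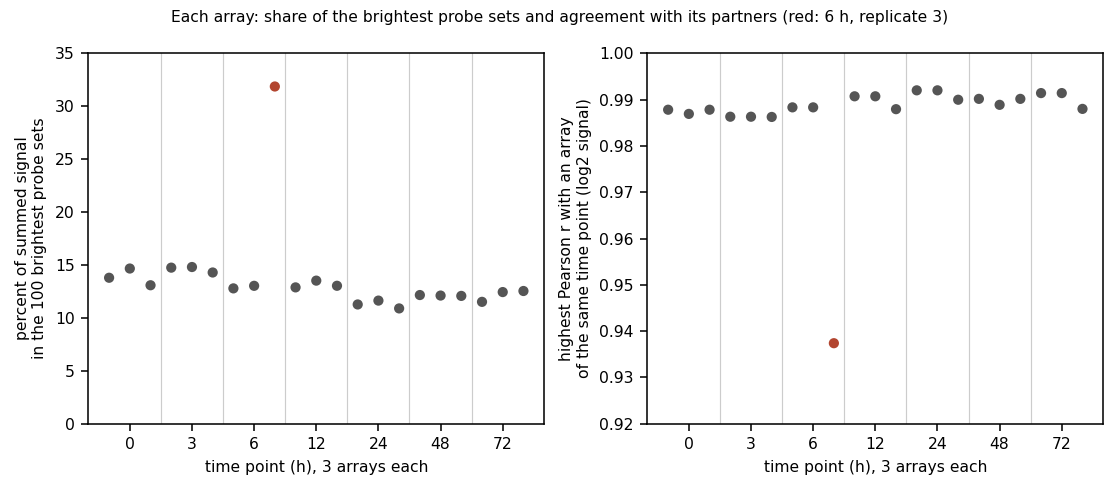
Each point is 1 array, grouped by time point in h. The left axis is the percent of the summed signal held by the 100 brightest probe sets. The right axis is the highest Pearson correlation of log2 signals with another array of the same time point. It was taken across probe sets with a mean signal over 200. Replicate 3 at 6 h, in red, lies at 31.9% and 0.937, and the other 20 arrays lie between 10.9% and 14.8%.

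Values below are log2 fold changes ± SE from limma against 0 h, with n = 3 arrays per time point, unless stated. Each SE rests on 1 spread per gene, estimated over all 21 arrays, so a gene has the same SE at every time. Replicate 3 at 6 h enters that spread, so an SE or p-value need not reflect the arrays of the time named. Of the genes that the rule for named genes picked, not all are printed. Their 209 values called as changed had all 3 arrays beyond all 3 arrays of 0 h, which their selection as called genes all but requires. Counts of list members adjusted over the list alone equalled those adjusted over all probe sets tested, except in 2 of 156 pairs of list and time: 2 chemokines instead of 1 were lower at 72 h, and 21 replication genes instead of 19 were higher at 72 h. Directions are relative to the trimmed mean of each array. Scaling the arrays to their poly-A controls instead, a choice made after seeing the data, shifted every gene by -0.85 at 3 h, -0.53 at 6 h, 0.60 at 12 h, 0.87 at 24 h, 1.04 at 48 h and 0.62 at 72 h. With that scaling 153 genes were higher and 4319 lower at 3 h, 465 and 3125 at 6 h, 2883 and 285 at 12 h, 4882 and 290 at 24 h, 5951 and 59 at 48 h, and 2317 and 46 at 72 h. The splits given below are those of the deposited scale. Every list median moves by the same shift, also where no effect of the poly-A scaling is stated below, so medians that keep their sign can still come close to 0.

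At 3 h the largest changes of single genes were rises. Atf3, a stress-induced transcription factor, rose by 7.43 ± 0.38, Cyp1a1, a target of the aryl hydrocarbon receptor, by 6.50 ± 0.29, and Fos, an early-response transcription factor, by 6.28 ± 0.16. Fgf21 and Gdf15, secreted stress hormones, rose by 5.88 ± 0.20 and 5.05 ± 0.20. Of 18 immediate early genes measured, 16 rose and none fell (median 3.46, camera adjusted p = 1.24e-24), among them Btg2 (4.88 ± 0.18) and Myc (4.83 ± 0.09). Cdkn1a, a p53 target that restrains the cell cycle, rose by 4.63 ± 0.16. The largest falls were those of Atp5if1 (-3.72 ± 0.30), Serpinb9b (-3.63 ± 0.45), Serpina7, the thyroxine-binding globulin (-3.10 ± 0.16), Cdh17 (-2.90 ± 0.15), Nup107 (-2.83 ± 0.45) and Abhd8 (-2.73 ± 0.53).

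Other lists had also moved at 3 h. Targets of NRF2 and glutathione genes had 11 of 20 members higher (median 1.08, adjusted p = 1.59e-07), and the endoplasmic reticulum and integrated stress response list had 8 of 17 higher (median 0.89, adjusted p = 1.23e-07). Of 12 heat shock genes, 5 were higher (median 0.88), with an adjusted p of 0.000202, and of 0.19 with an estimated correlation. The NRF2, stress response and heat shock medians were only 0.23, 0.04 and 0.03 with the poly-A scaling. Targets of p53 had 5 of 13 higher (median 0.78), chemokines and cytokines 5 of 16 higher and 1 lower (median 0.70), and stellate cell and matrix genes 4 of 22 higher and 1 lower (median 0.61), and all 3 medians were below 0 with the poly-A scaling. The camera adjusted p-values of these 3 lists were 8.08e-07, 0.000817 and 4.45e-05. Ribosome biogenesis genes had a median of 0.25 and the G2 and mitosis list one of 0.43, both below 0 with the poly-A scaling, with 0 of 18 and 3 of 22 members higher (adjusted p = 0.00107 and 0.00356). Macrophage markers had a median of -0.42 with 0 of 19 members called (adjusted p = 0.000464), and bile acid genes one of -0.43 with 1 of 17 lower (adjusted p = 0.00462, and 0.0718 with an estimated correlation). Neutrophil markers had a median of 0.60, which was below 0 with the poly-A scaling, with 0 of 6 called (adjusted p = 0.0368, and 0.19 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.0624), without 0 h replicate 2 (0.0545) and without 3 h replicate 1 (0.0687). Plvap and Tie1, both markers of endothelial cells, went opposite ways, at -2.23 ± 0.40 and 1.25 ± 0.16. The list of 13 sinusoidal endothelial markers was not called at any time with all arrays and the reported settings (adjusted p = 0.0821 at 3 h). At 3 h it was called without 6 h replicate 3 (adjusted p = 0.0477) and with the probe set of largest variance (0.0489).

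In all, 824 of 10405 genes were called at 3 h, 484 higher and 340 lower, and 12 of 26 lists. The named genes called at 3 h had adjusted p-values of at most 0.000429. With 32 added to each signal, the values of Atf3, Cyp1a1, Fos, Nup107 and Abhd8 were 6.63, 5.65, 5.33, -1.64 and -1.79, because these genes had mean signals below 69.4 at 1 of the 2 times. The smaller values are the safer ones. By them Plvap (-1.94) and Cyp7a1 (-1.86) fell further than Nup107 and Abhd8. Atf3 was at 6.64 without 0 h replicate 3, Plvap at -1.42 without 3 h replicate 2 and Atp5if1 at -4.31 without 3 h replicate 3.

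**Figure D2:**
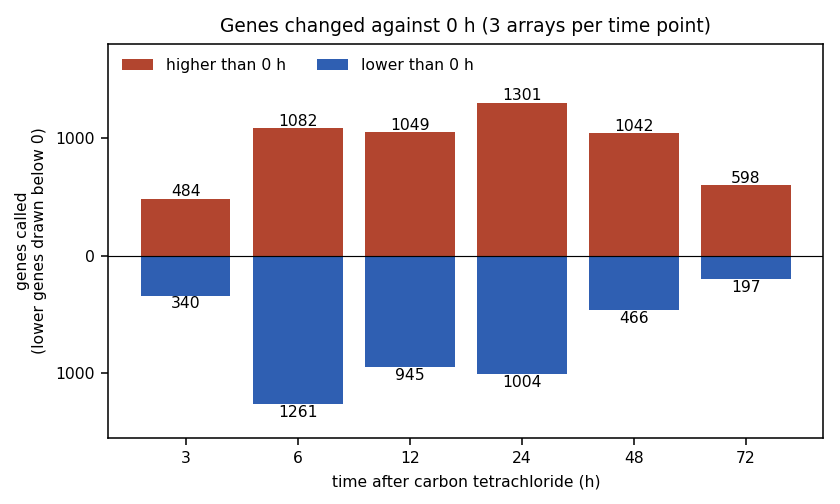
Bars give the number of genes called against 0 h at each time in h (limma adjusted p under 0.05 and a log2 fold change of at least 1 in size, 3 arrays per time point), higher genes above the line and lower genes below it. The number of higher genes was 484 at 3 h and 1301 at 24 h, and with the poly-A scaling 153 and 4882.

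At 6 h the oxidative, heat shock and nucleolar lists had risen. Of 20 NRF2 and glutathione genes, 14 rose (median 1.71, camera adjusted p = 6.04e-09), among them Srxn1 (5.57 ± 0.24), Slc7a11, a cystine transporter (5.56 ± 0.24), Hmox1, which degrades haem (4.99 ± 0.30), and Txnrd1 (3.87 ± 0.26). Of 12 heat shock genes, 11 rose (median 2.34, adjusted p = 4.2e-07, and 0.0821 with an estimated correlation), among them Bag3 (4.31 ± 0.20), Hspb8 (4.04 ± 0.24), Dnajb1 (3.94 ± 0.15) and Hspb1 (2.64 ± 0.16). Of 18 ribosome biogenesis genes, 14 rose (median 1.39, adjusted p = 1.48e-10), with Nop56 at 2.74 ± 0.12, Nop58 at 2.43 ± 0.10, Mybbp1a at 1.82 ± 0.15 and Nolc1 at 1.67 ± 0.11. Among the single genes with the largest rises were Phlda1 (7.65 ± 0.51), Atf3 (7.20 ± 0.38), Zfand2a, a stress-induced zinc finger protein (6.69 ± 0.26), PVR, the poliovirus receptor (5.93 ± 0.21), and Srxn1. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 6.44 on the log2 scale (SE 0.23). The next largest falls were those of Serpinb9b (-5.47 ± 0.45), Hdhd3 (-4.61 ± 0.13), Rab40b (-4.18 ± 0.55), Lgr4, a receptor for R-spondins (-3.97 ± 0.49), and Dbp, a clock-controlled transcription factor (-3.94 ± 0.31).

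Immediate early genes stayed high at 6 h, with 17 of 18 higher (median 3.44, adjusted p = 3.01e-14). The stress response list had 11 of 17 higher (median 1.57), chemokines and cytokines 11 of 16 and p53 targets 7 of 13 higher and 1 lower (median 1.34), with adjusted p-values of 6.06e-07, 1.25e-05 and 8.44e-05. Stellate cell and matrix genes had 8 of 22 higher and 1 lower (median 0.76, adjusted p = 4.58e-06). Of the metabolic lists, bile acid genes had 12 of 17 lower (median -1.32, adjusted p = 4.2e-07), cholesterol synthesis 9 of 20 lower and 2 higher (median -0.82, adjusted p = 0.00336), urea cycle and amino acid genes 8 of 21 lower and 1 higher (median -0.59, adjusted p = 0.00952) and pericentral genes 5 of 12 lower (median -0.82, adjusted p = 0.00439). With an estimated correlation the adjusted p was 0.0638 for cholesterol synthesis, 0.405 for the urea cycle list and 0.196 for pericentral genes. The P450 list had 7 of 23 lower and 1 higher (median -0.35) and fatty acid oxidation 2 of 18 lower (median -0.35). Both had an adjusted p of 0.0227, with 0.264 and 0.363 with an estimated correlation, and both calls ended without 6 h replicate 1 (adjusted p = 0.0557 and 0.0686) and without 6 h replicate 2 (0.0924 and 0.0762).

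Positive acute phase proteins at 6 h had 8 of 22 members higher and 1 lower, with a median of 0.65 (adjusted p = 0.000906, and 0.407 with an estimated correlation). That median was -0.14 without replicate 3 at 6 h and 0.04 with quantile normalization. Lcn2 was at 3.68 ± 0.10, A2m at 1.80 ± 0.07 and Hamp, the iron hormone hepcidin, at 1.81 ± 0.36. Secreted hepatocyte proteins had a median of 0.35 with 0 of 21 called (adjusted p = 0.567), which was -0.27 without that array, -0.12 with quantile normalization and below 0 with the poly-A scaling. The secreted list was called without that array (adjusted p = 0.00107) and with quantile normalization (0.0309). Neutrophil markers had a median of 0.64 with 1 of 6 higher, and G2 and mitosis genes, whose median lay below 0 with the poly-A scaling, one of 0.52 with 2 of 22 higher (adjusted p = 0.044 and 0.0339). With an estimated correlation these were 0.197 and 0.131. Both calls ended with quantile normalization (adjusted p = 0.0583 and 0.0572), without 0 h replicate 2 (0.0579 and 0.0524) and without 6 h replicate 1 (0.0769 and 0.0519), and that of the neutrophil markers also without 6 h replicate 2 (0.0521).

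In all, 2343 genes were called at 6 h, 1082 higher and 1261 lower, and 2137 without replicate 3 at 6 h, 1088 higher and 1049 lower. Without it the values of Hmox1, Hamp and Rab40b were 4.36, 1.05 and -3.06, and Lgr4 fell by 3.00 on the log2 scale, while without 6 h replicate 2 Lgr4 was at -4.69. Alb, which encodes albumin and was not called at 6 h (0.69 ± 0.41), was at -0.15 without it, and was called at 1.16 without replicate 1 and at 1.07 without replicate 2. The named genes called at 6 h had adjusted p-values of at most 0.000259. With 32 added to each signal Phlda1, Atf3, Serpinb9b, Rab40b, Lgr4 and Dbp were at 6.33, 6.40, -4.16, -3.26, -3.18 and -3.02. Phlda1 was at 8.26 without 0 h replicate 1 and 6.87 without 0 h replicate 2, and Atf3 at 6.42 without 0 h replicate 3.

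At 12 h the endoplasmic reticulum and integrated stress response reached its highest median, and sterol synthesis its lowest on the deposited scale, although with the poly-A scaling its median was lower at 6 h (-1.36) than at 12 h (-0.74). Of 17 stress response genes, 13 rose (median 2.08, camera adjusted p = 5.93e-09), among them Atf3 (6.45 ± 0.38), Trib3 (3.74 ± 0.20), Ppp1r15a, a regulator of eIF2 phosphorylation (3.51 ± 0.14), and Ddit3, the factor CHOP (3.17 ± 0.13). Of 20 cholesterol synthesis genes, 14 fell and 1 rose (median -1.34, adjusted p = 3.83e-09), with Msmo1 at -3.61 ± 0.10, Hmgcs1 at -3.23 ± 0.11, Idi1 at -2.37 ± 0.11 and Nsdhl at -2.20 ± 0.06. Among the largest single rises were those of Atf3, Cyp1a1 (6.19 ± 0.29), Grhl1 (5.78 ± 0.36), Phlda1 (5.75 ± 0.51) and Zfand2a (5.70 ± 0.26). Cyp7a1 was at -7.10 ± 0.23, with -6.50 at 12 h and -6.98 at 6 h with the poly-A scaling, so the time of its lowest level depends on the scaling, and other large falls were those of Nrep (-3.77 ± 0.15), Hdhd3 (-3.77 ± 0.13), Avpr1a, the vasopressin receptor of the liver (-3.75 ± 0.12), and Msmo1.

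Ribosome biogenesis had 17 of 18 members higher at 12 h (median 1.37, adjusted p = 1.02e-10), NRF2 and glutathione genes 15 of 20 (median 1.58, adjusted p = 4.55e-10), immediate early genes 17 of 18 (median 2.67, adjusted p = 1.36e-13), and chemokines and cytokines 13 of 16 (median 1.96, adjusted p = 6.99e-07). Heat shock genes had 9 of 12 higher (median 1.69, adjusted p = 1.99e-05, and 0.134 with an estimated correlation). Targets of p53 had 6 of 13 higher and 1 lower (median 0.77, adjusted p = 0.0014), and stellate cell and matrix genes 5 of 22 higher and 1 lower (median 0.43, adjusted p = 0.00174). Bile acid genes had 11 of 17 lower (median -1.04, adjusted p = 3.45e-08) and pericentral genes 6 of 12 lower (median -0.99, adjusted p = 1.85e-05, and 0.0649 with an estimated correlation). The P450, urea cycle, fatty acid oxidation and periportal lists had medians of -0.59, -0.52, -0.35 and -0.48, all above 0 with the poly-A scaling. Their adjusted p-values were 0.00694, 0.000612, 0.0124 and 0.0153, and with an estimated correlation 0.197, 0.28, 0.334 and 0.259. G2 and mitosis genes had 4 of 22 higher (median 0.53, adjusted p = 0.0157, and 0.092 with an estimated correlation). Cyp2e1, the enzyme that activates carbon tetrachloride, was lower at -1.03 ± 0.19. That call ended with quantile normalization (-0.95), with median centring (-0.90) and without 0 h replicate 2 (-0.99).

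In all, 1994 genes were called at 12 h, 1049 higher and 945 lower. The named genes called at 12 h had adjusted p-values of at most 0.000132. With 32 added to each signal Atf3, Cyp1a1, Grhl1 and Phlda1 were at 5.66, 5.35, 4.27 and 4.46. Phlda1 was at 6.37 without 0 h replicate 1 and 4.98 without 0 h replicate 2, and Atf3 at 5.67 without 0 h replicate 3.

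At 24 h chemokine and cytokine genes were at their highest median, and many genes of liver metabolism were lower than at 0 h. On the deposited scale the P450, bile acid, urea cycle and fatty acid oxidation lists had their lowest medians then, but with the poly-A scaling the last 3 were lowest at 6 h (-1.85, -1.12 and -0.89). Of 16 chemokines and cytokines, 11 rose (median 2.25, camera adjusted p = 2.12e-06), among them the monocyte attractants Ccl2 (6.45 ± 0.14) and Ccl7 (5.71 ± 0.51), the decoy receptor Il1r2 (4.02 ± 0.34) and Ccl3 (3.39 ± 0.16). Among the other largest rises were those of Hspb1, a small heat shock protein (6.53 ± 0.16), Spp1, or osteopontin (6.50 ± 0.22), Fabp4, a fatty acid binding protein of macrophages and fat cells (6.07 ± 0.52), and Phgdh, the entry enzyme of serine synthesis (5.76 ± 0.19). Of 17 bile acid genes, 13 fell (median -2.40, adjusted p = 2.7e-12), with Cyp7a1 at -6.84 ± 0.23, Nr0b2 at -4.33 ± 0.29, the bile acid transporter Slc10a1 at -4.14 ± 0.08 and Slc27a5 at -3.56 ± 0.09. Of 23 P450 and drug metabolism genes, 18 fell and Cyp1a1 rose by 5.24 ± 0.29 (median -1.91, adjusted p = 1.3e-10), with Fmo1 at -6.33 ± 0.26, Cyp3a2 at -3.21 ± 0.19 and Cyp2e1 at -3.09 ± 0.19. Other large falls were those of A1bg (-6.78 ± 0.11), Cpa1 (-6.57 ± 0.25) and Gstp3 (-5.64 ± 0.14).

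By zone of the lobule, 11 of 12 pericentral genes fell at 24 h (median -2.22, adjusted p = 4.19e-10), among them Car3 (-5.11 ± 0.21), Rgn (-3.69 ± 0.09) and Oat (-3.32 ± 0.12), and Glul, glutamine synthetase, fell by 1.43 (SE 0.07). Of 16 periportal genes, 6 fell and 1 rose, with a median of -0.73 that lay above 0 with the poly-A scaling (adjusted p = 4.45e-06), and Aldh1b1 was at -3.08 ± 0.20 and Gls2 at -1.65 ± 0.07. Of 21 urea cycle and amino acid genes, 10 fell (median -0.90, adjusted p = 7.96e-10, and 0.0718 with an estimated correlation), with Sds at -4.64 ± 0.10, Bhmt at -4.54 ± 0.10, Otc at -4.14 ± 0.13 and Kmo at -2.84 ± 0.12. The urea cycle median was -0.03 with the poly-A scaling. Cholesterol synthesis had 15 of 20 lower (median -1.28, adjusted p = 2.54e-10). Fatty acid oxidation had 7 of 18 lower (adjusted p = 0.000152, and 0.158 with an estimated correlation), with Ehhadh at -4.66 ± 0.09, Hadh at -1.71 ± 0.16, Cpt1a at -1.66 ± 0.08 and Acadm at -1.29 ± 0.08. Gluconeogenesis and glycogen genes had 5 of 13 lower (adjusted p = 4.69e-05), with Pygl at -2.48 ± 0.07 and Pc at -2.04 ± 0.14. Secreted hepatocyte proteins had 6 of 21 lower (adjusted p = 0.000525, and 0.441 with an estimated correlation), with Apoa2 at -2.27 ± 0.24, Proc at -1.59 ± 0.13, Igf1 at -1.56 ± 0.18 and F2 at -1.16 ± 0.24, whose call ended with quantile normalization (-0.94). The medians of these last 3 lists, -0.59, -0.68 and -0.70, lay above 0 with the poly-A scaling. Alb was not called at any time, at -0.38 ± 0.41 at 24 h.

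Markers of other cells differed in size at 24 h. Of 6 neutrophil markers, 4 were higher (median 1.54, adjusted p = 0.00331, and 0.0733 with an estimated correlation), with S100a8 at 2.53 ± 0.09, S100a9 at 2.06 ± 0.11 and Csf3r at 1.54 ± 0.20. Of 19 macrophage markers, 8 were higher and 2 lower (median 0.39, adjusted p = 0.152). Of 13 lymphocyte markers, 3 were higher (median 0.62, adjusted p = 0.319), with Cd3d at 1.48 ± 0.35, Cd8a at 1.41 ± 0.27 and Cd3g at 1.13 ± 0.19, which was no longer called without 0 h replicate 1 (0.90). The lymphocyte list was not called at any time. Cholangiocyte and progenitor genes had 4 of 8 higher and 1 lower (median 0.76, adjusted p = 0.284), with Cd24 at 2.11 ± 0.22, Krt8 at 1.53 ± 0.09 and Afp at -1.53 ± 0.22. Sinusoidal endothelial markers had 2 of 13 higher and 2 lower. Stellate cell and matrix genes had 7 of 22 higher and 1 lower (median 0.57, adjusted p = 0.0237, and 0.0821 with an estimated correlation). That call ended with quantile normalization (adjusted p = 0.0572) and without replicate 3 at 6 h (0.0594). Timp1, an inhibitor of matrix proteases, rose by 3.45 ± 0.10.

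Stress lists remained called at 24 h: 13 of 17 stress response genes (median 1.30, adjusted p = 3.2e-07), 7 of 12 heat shock genes (median 1.41, adjusted p = 0.000361, and 0.198 with an estimated correlation), 11 of 18 immediate early genes (median 1.62, adjusted p = 2.12e-06), 14 of 18 ribosome biogenesis genes (median 1.36, adjusted p = 2.03e-08) and 9 of 20 NRF2 and glutathione genes (median 0.73, adjusted p = 0.00748, and 0.194 with an estimated correlation) were higher, and 1 NRF2 and glutathione gene was lower. Targets of p53 had 7 of 13 higher and 1 lower (median 1.42, adjusted p = 0.0525), with Cdkn1a at 3.31 ± 0.16, Gadd45a at 3.00 ± 0.30, Tp53inp1 at 1.97 ± 0.13 and Sesn1 at -2.32 ± 0.22. The p53 list was called with quantile normalization (adjusted p = 0.0376) and without any 1 of several arrays, among them 6 h replicate 3 (0.0428). Of 24 replication genes, 11 were higher and 1 lower (median 0.98, adjusted p = 0.00264), Ccnd1, the G1 cyclin, was at 2.08 ± 0.14, and Ccnb1, the mitotic cyclin, at 0.06 ± 0.20. In all, 2305 genes were called at 24 h, 1301 higher and 1004 lower. The named genes called at 24 h had adjusted p-values of at most 0.00134. With 32 added to each signal Ccl7, Il1r2, Fabp4, Phgdh, Cyp1a1, Nr0b2 and Fmo1 were at 4.85, 3.26, 5.04, 4.89, 4.41, -3.67 and -5.61. Fabp4 was at 5.08 without 0 h replicate 1 and 6.85 without 0 h replicate 2.

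**Figure D3:**
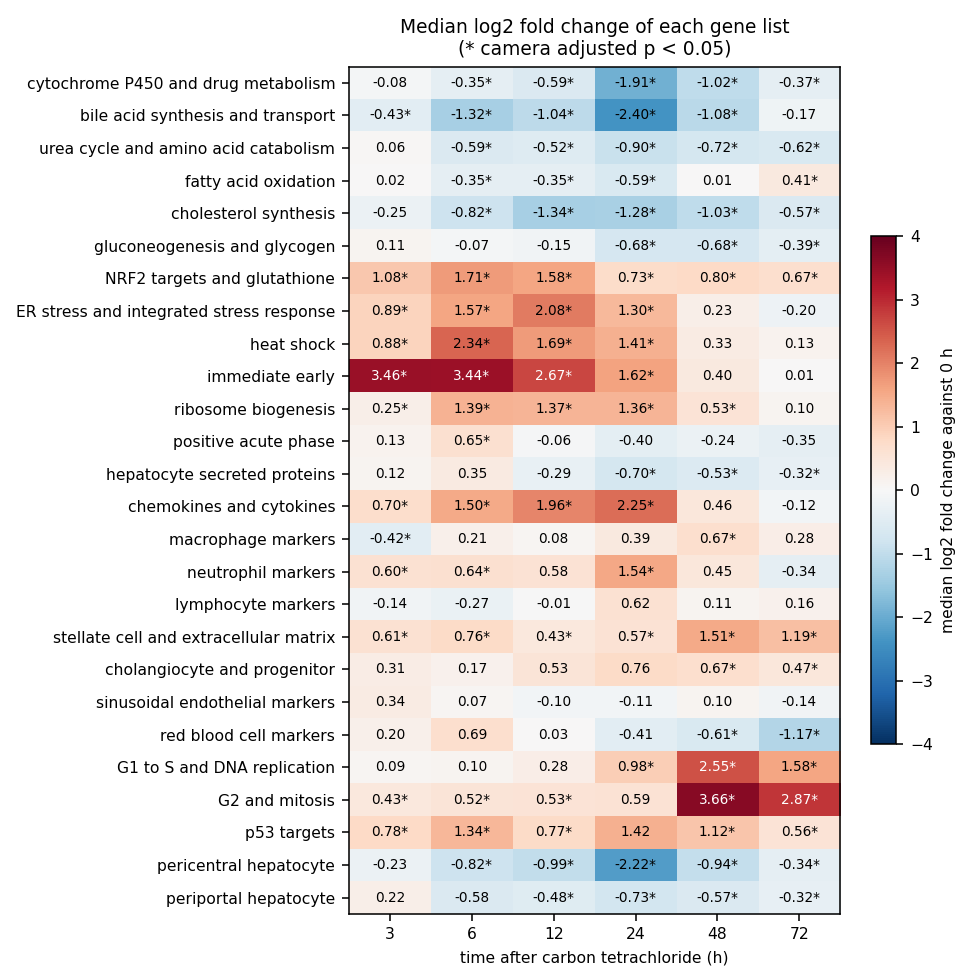
Each row is a gene list fixed before the data were examined and each column a time in h; cells give the median log2 fold change of its members against 0 h, with an asterisk where camera's adjusted p was under 0.05. The immediate early list is highest at 3 h (3.46), the G2 and mitosis list at 48 h (3.66) and the bile acid list lowest at 24 h (-2.40). With the poly-A scaling the immediate early list is highest at 12 h (3.27) and the bile acid list lowest at 6 h (-1.85). Lists whose median is opposite in sign to the poly-A shift and smaller in size, such as the periportal list at 24 h, change sign with that scaling.

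At 48 h nearly all listed genes of the cell cycle were higher. Of 24 genes of G1 to S and DNA replication, 23 rose (median 2.55, camera adjusted p = 1.61e-13), among them Ccne2 (5.67 ± 0.19), Rrm2, a subunit of ribonucleotide reductase (5.18 ± 0.08), E2f1 (4.12 ± 0.22) and Mcm3 (3.88 ± 0.33). All 22 G2 and mitosis genes rose (median 3.66, adjusted p = 5.73e-14), among them Pbk (6.25 ± 0.64), Ccna2 (5.28 ± 0.20), Cdk1 (4.63 ± 0.16) and Mki67, the proliferation marker (4.33 ± 0.16), and Ccnb1 was at 3.31 ± 0.20. The largest single rises were those of Acot1, an acyl-CoA thioesterase (9.83 ± 0.52), Fabp4 (6.64 ± 0.52), Spp1 (6.53 ± 0.22), Pbk, Ckap2 (6.15 ± 0.46) and Knstrn (5.76 ± 0.43), the last 3 being mitotic genes. Of 22 stellate cell and matrix genes, 13 rose (median 1.51, adjusted p = 1.52e-07), with Tgfb1 at 5.53 ± 0.25, Tagln at 3.40 ± 0.25, Timp1 at 2.93 ± 0.10 and Vim at 2.84 ± 0.08. Of 19 macrophage markers, 8 rose (median 0.67, adjusted p = 0.0014), with Gpnmb at 4.24 ± 0.08, Tyrobp at 2.59 ± 0.11, Itgam at 1.86 ± 0.28 and Cd53 at 1.85 ± 0.07. Cd68, at 1.02 ± 0.09, was no longer called with median centring (0.96), nor without 0 h replicate 1 (0.98), 0 h replicate 3 (0.99) or 48 h replicate 1 (0.98). A2m, the acute phase protein alpha-2-macroglobulin, was at its highest at 4.32 ± 0.07, while its list had 2 of 22 members higher and 1 lower (adjusted p = 0.751). Without 6 h replicate 3 that list was called, with a median of -0.24 (adjusted p = 0.0439).

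The largest falls at 48 h were those of Serpinb9b (-6.25 ± 0.45), Cyp2c11, a male-specific P450 (-4.08 ± 0.19), Stac3 (-4.05 ± 0.22), Obp3 (-3.78 ± 0.11), Inmt (-3.78 ± 0.32) and Ahsp, a stabiliser of alpha globin (-3.63 ± 0.63). Bile acid genes had 10 of 17 lower (median -1.08, adjusted p = 3.38e-10). Their median was -0.04 with the poly-A scaling. The P450 list had 12 of 23 lower and 2 higher (median -1.02, adjusted p = 1.59e-07), cholesterol synthesis 10 of 20 lower (median -1.03, adjusted p = 2.18e-11) and pericentral genes 5 of 12 lower (median -0.94, adjusted p = 9.44e-07), and these 3 medians lay above 0 with the poly-A scaling. So did those of the urea cycle (-0.72, adjusted p = 1.34e-08), gluconeogenesis (-0.68, 1.17e-05), secreted protein (-0.53, 0.00188), periportal (-0.57, 0.000215) and red blood cell lists (-0.61, 0.036). With an estimated correlation the adjusted p was 0.0916 for the urea cycle, 0.492 for secreted proteins, 0.0983 for periportal genes and 0.0821 for red blood cell markers. NRF2 and glutathione genes had 8 of 20 higher (median 0.80, adjusted p = 0.00063, and 0.0983 with an estimated correlation), cholangiocyte and progenitor genes 2 of 8 higher (median 0.67, adjusted p = 0.007), and ribosome biogenesis genes 1 of 18 higher (median 0.53, adjusted p = 0.0041). Targets of p53 had 8 of 13 higher and 1 lower (median 1.12, adjusted p = 0.0449, and 0.163 with an estimated correlation). That call ended with the probe set of largest variance (adjusted p = 0.0959), with 32 added (0.052), and without 6 h replicate 2 (0.0554). In all, 1508 genes were called at 48 h, 1042 higher and 466 lower, with adjusted p-values of at most 0.000452 for the named genes. Ahsp was at -4.40 without 48 h replicate 1 and -2.34 without 48 h replicate 2, Fabp4 at 5.65 without 0 h replicate 1 and 7.42 without 0 h replicate 2, and Acot1 at 10.85 without the latter. With 32 added to each signal Acot1, Spp1, Fabp4, Pbk, Ckap2, Knstrn, Ccne2, E2f1, Mcm3, Tgfb1, Serpinb9b and Ahsp were at 7.07, 6.32, 5.60, 4.96, 4.89, 4.39, 4.93, 3.28, 3.29, 3.76, -4.46 and -2.42. Rrm2 was then at 5.06, above Pbk, Ckap2 and Knstrn, so the order of the largest rises depends on this choice.

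At 72 h proliferation and matrix genes were still high and, on the deposited scale, most metabolic lists were nearer to 0 h than at 48 h. With the poly-A scaling the P450, bile acid, cholesterol and pericentral medians were farther from 0 than at 48 h. Those of the urea cycle, fatty acid oxidation, gluconeogenesis, secreted protein and periportal lists were nearer. All 22 G2 and mitosis genes (median 2.87, camera adjusted p = 1e-17) and 19 of 24 replication genes (median 1.58, adjusted p = 1.36e-13) were higher, and Mki67 was at 3.56 ± 0.16. Of 22 stellate cell and matrix genes, 13 were higher (median 1.19, adjusted p = 2.18e-11), and Col1a1, the main chain of type I collagen, reached its largest value at 3.18 ± 0.11, after 2.48 ± 0.11 at 48 h and 0.62 ± 0.11 at 24 h. The largest rises were those of Acot1 (9.82 ± 0.52), Fabp4 (6.17 ± 0.52), Spp1 (5.83 ± 0.22), Ckap2 (5.36 ± 0.46), Pbk (5.27 ± 0.64) and Knstrn (5.19 ± 0.43). The largest falls were those of Serpinb9b (-5.96 ± 0.45), Obp3, a carrier protein that male rat liver secretes (-5.69 ± 0.11), Inmt (-3.83 ± 0.32), Cyp3a9 (-3.35 ± 0.11), Sds (-3.20 ± 0.10) and Cyp2c11 (-2.88 ± 0.19). Bile acid genes had 0 of 17 called (adjusted p = 0.0821), with a median of -0.17 that lay above 0 with the poly-A scaling, and Cyp7a1 was at -0.45 ± 0.23 and Cyp2e1 at -0.37 ± 0.19, neither of them called. The bile acid list was called without 6 h replicate 3 (adjusted p = 0.0232) and with the probe set of largest variance (0.0356).

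Of 5 red blood cell markers, 4 were lower at 72 h (median -1.17, adjusted p = 0.0108), with Ahsp at -2.25 ± 0.63, Hbb at -1.38 ± 0.32, Alas2 at -1.17 ± 0.10 and Hba-a2 at -1.11 ± 0.38 (adjusted p = 0.031). The call of Hba-a2 ended with quantile normalization and without each array of 0 h and of 72 h (values between -1.17 and -0.95). Fatty acid oxidation had 2 of 18 higher (median 0.41, adjusted p = 0.000152, and 0.158 with an estimated correlation). NRF2 and glutathione genes had 6 of 20 higher (median 0.67, adjusted p = 5.88e-05, and 0.0638 with an estimated correlation) and cholangiocyte and progenitor genes 1 of 8 higher (median 0.47, adjusted p = 0.0247, and 0.0649 with an estimated correlation). The P450, urea cycle, cholesterol, gluconeogenesis, secreted protein, pericentral and periportal lists had medians of -0.37, -0.62, -0.57, -0.39, -0.32, -0.34 and -0.32, each above 0 with the poly-A scaling. Their adjusted p-values were 0.000998, 2.63e-09, 9.68e-07, 0.00439, 0.032, 0.00832 and 0.00569, and with an estimated correlation 0.124, 0.0791, 0.00582, 0.113, 0.639, 0.224 and 0.204. The call of the secreted proteins ended without 0 h replicate 2 (adjusted p = 0.0686) and without 72 h replicate 1 (0.0577). Targets of p53 had 2 of 13 higher (median 0.56, adjusted p = 0.0481, and 0.169 with an estimated correlation). That call ended when any 1 of 9 arrays was left out (adjusted p = 0.0501 to 0.0585), with 32 added (0.0564) and with the probe set of largest variance (0.0591). Of the early lists, immediate early genes had 3 of 18 higher and 1 lower (adjusted p = 0.473), the stress response 1 of 17 (0.0943) and heat shock 3 of 12 (0.273). Without 6 h replicate 3 the stress response (median -0.20, adjusted p = 0.00514) and heat shock (median 0.13, 0.0445) were called. Both were also called with quantile normalization (0.0162 and 0.0139). Positive acute phase proteins were likewise called without that array (median -0.35, adjusted p = 7.78e-05). Atf3 was at 1.35 ± 0.38, a call that ended without 0 h replicate 3 (0.57), with 32 added (0.86) and with only the 2 groups compared, and Ccl2 at 1.22 ± 0.14, a call that ended without 0 h replicate 2 (0.98). In all, 795 genes were called at 72 h, 598 higher and 197 lower. With 32 added to each signal Acot1, Fabp4, Ckap2, Pbk, Knstrn and Serpinb9b were at 7.06, 5.13, 4.13, 4.01, 3.83 and -4.38. Fabp4 was at 5.18 without 0 h replicate 1 and 6.94 without 0 h replicate 2, and Acot1 at 10.84 without the latter.

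**Figure D4:**
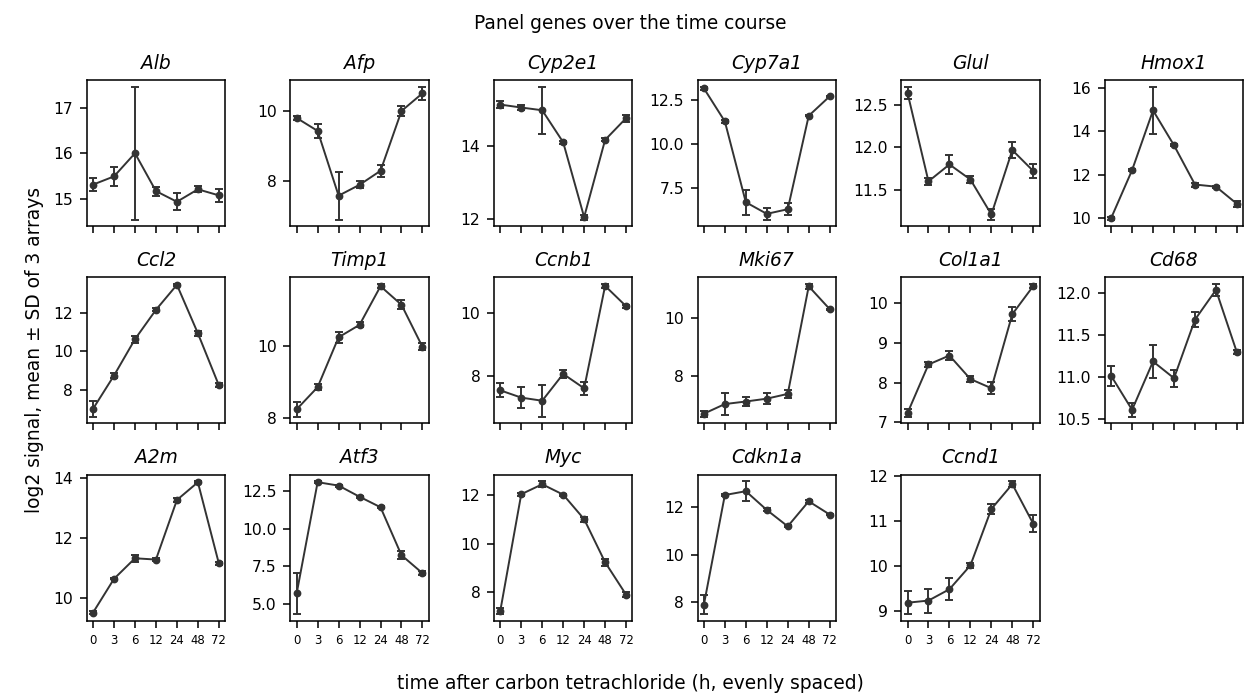
Points give the mean log2 signal of 3 arrays and bars the SD for 17 genes chosen before the data were examined, against time in h at even spacing. Atf3 and Myc were high from 3 h, Ccl2 was highest at 24 h, Mki67 and Ccnb1 rose at 48 h and Cyp7a1 was low at 6, 12 and 24 h.

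The profiles of different times were also compared with each other. Between 24 h and 6 h, 2258 genes differed, 1392 higher and 866 lower at 24 h, and 1905 without replicate 3 at 6 h, 1095 and 810. With the poly-A scaling the split was 7746 and 79. Immediate early genes were lower at 24 h in 14 of 18 and higher in 1 (median -1.44, and -0.05 with the poly-A scaling, camera adjusted p = 1.08e-08), the P450 list lower in 16 of 23 and higher in 1 (median -1.36, adjusted p = 1.01e-08), which was above 0 with the poly-A scaling, and replication genes higher in 12 of 24 (median 1.03, adjusted p = 0.00301). Between 72 h and 24 h, 1788 genes differed, 958 higher and 830 lower at 72 h, and with the poly-A scaling 659 and 1433. Bile acid genes were higher at 72 h in 14 of 17 and lower in 1 (median 1.78, adjusted p = 9.15e-13), fatty acid oxidation in 9 of 18 (adjusted p = 6.52e-10), and G2 and mitosis genes in 21 of 22 (median 2.42, adjusted p = 4.97e-11). Chemokines and cytokines were lower at 72 h in 13 of 16 (median -2.27, adjusted p = 1.01e-08), the stress response in 15 of 17 (median -1.65, adjusted p = 6.52e-10) and ribosome biogenesis in 15 of 18 (median -1.23, adjusted p = 6.52e-10).

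Over the whole course 4328 of 10405 genes (41.6%) passed the F-test with a change of at least 2-fold at 1 or more times. The largest change of these genes was a rise at 24 h in 691, at 6 h in 551 and at 48 h in 526, and a fall at 6 h in 787 and at 24 h in 617. These numbers hold for the deposited scale with all arrays. They were not counted with the poly-A scaling, which shifts each time by another amount, or without replicate 3 at 6 h. The order of the times may therefore depend on both choices. In the fit that took each time point as 1 value, with adjacent times as pairs, 1 gene was called for 3 and 6 h, 0 for 12 and 24 h, and 41 for 48 and 72 h, all of them higher. In that fit 0 h is a single value, and the spread comes only from the pairs, whose 2 times differ, so it is a weak test. At an unadjusted limma p under 0.05, where 5% of 10405 genes would pass by chance, the numbers were 1179, 1837 and 943. The authors' deposited table of log2 ratios gave the same sign for all 824 genes called at 3 h and for 2304 of the 2305 called at 24 h. In the mean of those ratios, 631 of these genes at 3 h and 2032 at 24 h also changed by at least 2-fold in that direction. The ratios were made from the same arrays, so this is no independent support.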

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

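The tests of the 3 patterns weighed below were chosen only after the results had been seen.

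Between 24 h and 72 h some values went from below to above the level of 0 h on the deposited scale. Aldh1b1, a mitochondrial aldehyde dehydrogenase, was at -3.08 ± 0.20 at 24 h and at 1.96 ± 0.20 at 72 h, a difference of 5.04 (limma adjusted p = 8.36e-14, 3 arrays per time point). The fatty acid oxidation list differed by a median of 1.0004 (camera adjusted p = 6.52e-10, and 0.0283 with an estimated correlation). Its median against 0 h was -0.59 at 24 h and 0.41 at 72 h, but 0.27 and 1.02 with the poly-A scaling, and with an estimated correlation both calls against 0 h were lost (adjusted p = 0.158 at each time).

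Replicate 3 at 6 h stood apart from its partners, and its hybridisation control cre had a mean signal of 115200, against 33866 and 33569 on the partners. An intensity-dependent scale as the whole cause is argued against, because its residual SD was 0.772 after quantile normalization, while the other 20 arrays reached at most 0.349. On the 100 probe sets brightest on the partners, its median excess went from 1.85 to -0.01 with that normalization. A part played by such a scale, above all in the brightest probe sets, is therefore not excluded by that test. The first form of that test asked for a slope against the partners within 0.9 to 1.1, which was met at 1.065, but a slope does not capture a curved relation and the other arrays spanned 0.945 to 1.02, so it was replaced after its value was seen and excludes nothing. A wrong label from another time point is argued against by the mean correlation with its partners, which exceeded that with any other time by 0.031. Only probe sets with a mean signal over 200 were used for it. For degraded RNA the 3' to 5' ratios do not decide, because they disagree. The Gapdh ratio of 1.13 lay within the range of the others. The beta-actin ratio of 3.71 was above theirs (at most 3.56), and the hexokinase ratio of 0.196 was below theirs (at least 0.737). What set this array apart stays open, and no biological explanation was tested.

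The poly-A controls, which the comparisons on the deposited scale do not use, had a mean log2 signal 0.849 above that of 0 h at 3 h and 0.669 above it at 6 h without replicate 3, and were 1.51-fold, 1.82-fold, 2.05-fold and 1.54-fold lower than at 0 h at 12, 24, 48 and 72 h. Hybridisation, staining or scanning is argued against, because the hybridisation controls varied between time points by 0.602 and the poly-A controls by 1.89. Another amount of control RNA per time point and another share of messenger RNA in the total RNA cannot be told apart. Both would leave the arrays of a time point close together, and their median range was 0.099, taken without replicate 3 at 6 h. The range was wider at 0 h (0.287) and at 48 h (0.444). At 48 h replicate 1 was at 8.93 and its partners at 9.37 and 9.34, so the shift at 48 h rests partly on 1 array. No measure of messenger RNA per total RNA was used here.

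Pericentral genes fell at 24 h by a median of 2.22 on the log2 scale. Their list shares Cyp7a1 with the bile acid list, so the falls of these lists are not separate evidence. A lower share of hepatocytes as the whole cause is argued against, because secreted hepatocyte proteins had a median of -0.70, above the upper quartile of -1.61 of the pericentral list. Loss of pericentral hepatocytes and lower expression within them cannot be told apart: the pericentral median lay below the periportal one by -1.49 (permutation test of list membership, one-sided p = 0.0236, 100000 resamples, 12 and 16 genes, which are not independent), but Glul, known mainly from the hepatocytes next to the central vein, was at -1.43 ± 0.07, against a median of -2.43 for the other members. The first form of this test let Glul alone decide and by it loss of these cells as the whole cause was argued against; it was replaced after the value had been seen, because 1 gene stood for the whole list, and whether other cells express Glul here was not tested. A reader who holds to the first form would take cell loss as the whole cause to be argued against, but by 1 probe set of 1 gene, which cannot exclude it. The Glul probe set of largest variance fell further at 6 h (-1.23 against -0.84) and at 72 h (-1.26 against -0.92). The test at 24 h was not repeated with that probe set.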

How the results depend on the processing

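Array weights, a filter at 1 or more time points and the poly-A scaling were added after seeing the data. Over the alternatives other than the poly-A scaling, values of named genes stayed on the same side of the threshold in 8090 cases, lost the call in 24, gained it in 6 and reversed in 0. List medians, not run with every alternative, did so in 3817, 34, 46 and 3 cases. Many cases in both tallies left out an array of neither time compared. There the fold change could not move and only the p-value could, so the tallies overstate how stable the values are. Apart from the panel, the named genes were also picked because they were called. A change of sign counts as a reversal here only if the value was called before or after it. In all, 24 list medians and 14 gene values changed sign, 3 and 0 of them called, and median centring, not in the tally of lists, turned 5 medians, 0 of them called as reported. The 3 reversals were secreted proteins at 6 h with quantile normalization (-0.12) and without 6 h replicate 3 (-0.27), and positive acute phase proteins at 6 h without 6 h replicate 3 (-0.14). With each array left out in turn these medians ranged from -0.27 to 0.68 and from -0.14 to 1.05. The cause was not tested. The poly-A scaling is not in these tallies: it turned the sign of 60 of 156 list medians and of 16 of 247 values of named genes, 0 of them among the 209 called values, and brought 21 called values under the fold limit.

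With an estimated correlation, 8, 9, 11, 11 and 5 lists were called at 6, 12, 24, 48 and 72 h, and with fry 19 at 3 h. Fry does not compare a list with other genes. Without the filter 2 genes were called for 3 and 6 h as a phase. With no fold limit 4043, 6137, 5685, 5885, 5036 and 3682 genes were called at 3 to 72 h, 6142 for 24 h against 6 h, 5368 for 72 h against 24 h and 8765 by the F-test, because smaller changes then count. With the poly-A scaling the numbers were 4472, 3590, 3168, 5172, 6010 and 2363, then 7825 for 24 h against 6 h and 9418 by the F-test, because it shifts all genes of a time together.

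With each array left out the counts were 816 to 881 at 3 h, 2137 to 2584 at 6 h, 1944 to 2055 at 12 h, 2263 to 2349 at 24 h, 1467 to 1551 at 48 h and 787 to 840 at 72 h. They were 1905 to 2583 for 24 h against 6 h, 1757 to 1834 for 72 h against 24 h and 4257 to 4532 by the F-test. The lists called were 12 to 16, 13 to 18, 16 to 17, 18 to 19, 16 to 19 and 13 to 19 at 3 to 72 h. Without 6 h replicate 3 they were 16, 18, 17, 19, 19 and 19. Residuals of 63 pairs of arrays with the same replicate number correlated across probe sets at -0.192 to 0.203, 14 of them over 0.1, and 13 of 21 arrays correlated best with their own number. Between 12, 24, 48 and 72 h all these values were above 0 (0.0233 to 0.192), and each comparison of 2 of these times had a pair over 0.1, which hints at a shared factor there. Over all times most of the 63 pairs stayed under 0.1, so the numbers were not taken as pairs. With the number as a block 829, 2349, 1998, 2309, 1511 and 804 genes were called at 3 to 72 h, and 16 and 14 lists at 48 and 72 h. The p53 targets were then no longer called at 48 h (camera adjusted p = 0.0518) or at 72 h (0.0531). Of 247 values of named genes, 32 added to the signal moved 47 by over 1.5-fold, and 45 of these had a signal under 69.4 at 1 of the times, so signal over background limits the size of these changes.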

Other observations

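Apart from the test of the clock genes and the splits of the arrays, the tests here were added after part of the data had been seen, and the 9 further lists were fixed before their values were examined and were adjusted over 9 lists and 6 times. Cytoskeleton and cell shape genes were higher at 24 h in 17 of 22 (median 1.98, camera adjusted p = 1.01e-09), at 48 h in 17 (median 2.21, adjusted p = 1.27e-12) and at 72 h in 13 (median 1.25, adjusted p = 6.4e-12). Tubb6, a tubulin, was already at 5.09 ± 0.19 at 6 h, and Anxa2 was at 3.87 ± 0.14 at 24 h. Translation initiation factors and tRNA synthetases were higher in 10 of 21 at 6 h (adjusted p = 4.56e-10) and 10 of 21 at 24 h (median 0.91, adjusted p = 6.35e-07), with Eif6 at 1.88 ± 0.13 at 6 h. Proteasome genes were higher in 9 of 30 at 12 h (median 0.75, adjusted p = 5.84e-11). Glycolysis genes were higher in 7 of 16 at 24 h (median 0.93, adjusted p = 0.000393), with the lactate transporter Slc16a3 at 3.42 ± 0.38 and Pkm at 2.98 ± 0.11. These calls held with an estimated correlation. Example genes here were chosen after their values were seen.

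Interferon response genes were lower in 6 of 21 at 48 h, with a median of -0.57 that lay above 0 with the poly-A scaling (adjusted p = 0.000145, and 0.0399 with an estimated correlation), and Mx2 was at -2.16 ± 0.29. They were also lower in 3 of 21 at 3 h (median -0.40, adjusted p = 0.000702) and at 72 h (median -0.20, above 0 with the poly-A scaling, adjusted p = 0.0311), with 0.0633 and 0.276 as adjusted p with an estimated correlation, while at 24 h 3 were higher and 0 lower (median 0.21, adjusted p = 0.133). Metallothionein and iron genes were higher in 6 of 10 at 6 h (median 1.13, adjusted p = 0.0186, and 0.548 with an estimated correlation). Oxidative phosphorylation genes were lower in 3 of 32 at 6 h (median -0.46, adjusted p = 0.00313, and 0.538 with an estimated correlation). Cytosolic ribosomal proteins were higher in 1 of 46 at 24 h (median 0.53, adjusted p = 0.00159, and 0.735 with an estimated correlation). The clock list was not called at any time.

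The hour of the day at which each liver was taken may have moved clock genes, a hypothesis written down before the values of their list were examined, although Dbp at 6 h had been seen. If 0 h and 24 h fell at the same hour, the median size of their change at 24 h should have been under 50% of that at 12 h. It was 0.87 at 24 h and 0.94 at 12 h, then 0.55 at 48 h and 0.51 at 72 h, which decides neither way. Of 2 members chosen after their values were seen, Nr1d1 was at -2.43, -2.45 and -2.33 at 24, 48 and 72 h and at 0.12 at 12 h. Per2, the other, was at 1.26, 1.08 and 1.65 at those 3 times and at -1.66 at 12 h. The hour of day is not given in the labels, so time of day and treatment cannot be told apart.

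Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split called 826, 2090, 2017, 2345, 1543 and 830 genes at 3 to 72 h when only the 2 times were fitted, 2007 for 24 h against 6 h and 1845 for 72 h against 24 h, and the highest of the other splits called 0 in each; 1 of the 10 splits reached the real number. For the F-test 1 of 100 splits of the 21 arrays, the real one, reached the real 4328 genes, and the highest other gave 331. Splits that mix times put the differences between times into the residual spread, which lowers their counts. Any difference between the samples of 2 times favours the real grouping. The splits therefore set the counts apart from noise between arrays only, and they do not exclude chance differences between rats. As technical replicates per the labels, the arrays of a time point cannot show whether rats differ as much.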
